A study of Oryctolagus cuniculus with 9 samples.

How the data were processed

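Polyadenylated RNA from rabbit (Oryctolagus cuniculus) vocal fold tissue was sequenced in 9 libraries. There were 3 libraries from normal folds without injury, 3 from injured folds left untreated and 3 from injured folds given a hydrogel called SOT, a name that the labels do not expand. Injured tissue was taken 1 week after injury, per the series' design text. The labels name the cell type as vocal cord histiocytes, while the tissue label and the design text describe the vocal fold, so the libraries were treated as whole tissue. The labels do not say that the replicates are separate animals, so the p-values measure the spread between these samples, which may be technical in part.

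Cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR of an unstated version were used with the genome build OryCun2.0, per the submitters' processing notes. Which step each tool performed, the sequencing instrument settings, the strandedness of the libraries and the handling of reads that match several genes are not given in the sources used here. The deposited table held 20525 genes, each with a read count and an FPKM value in every library, per the file headers, together with gene descriptions, positions and annotation terms. The deposited count columns held whole numbers, and a deposited FPKM was 0 exactly where the deposited count was 0. Between 53 and 79 genes per library had a deposited count of 1, between 101 and 115 had a count of 2 and between 350 and 419 had a count of 4. Such a pattern can arise when counts are rebuilt from coverage, which the sources do not state. Near-identical gene copies, such as the CD300 (CMRF35-like) family, keratins and myosin heavy chains, may share reads, and their values are uncertain to that extent. Of 5734 genes named only by a locus number, 595 were given a symbol from a RefSeq table of another assembly, mOryCun1.1, which was used for names alone.

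Total counts were between 44755718 and 45521838 in the normal libraries, between 49771566 and 50338111 in the untreated libraries and between 48444181 and 49434268 in the SOT libraries. A gene without counts in a library was given a floor of 3 counts, which corresponds to between 0.0558 and 0.0692 normalised counts (CPM, edgeR). Folds against a group whose libraries were all at 0 are stated as lower bounds against that floor per library. Floors cover counting error only, because reads without molecular identifiers are not independent molecules.

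Counts were analysed in R 4.3.3 with edgeR 4.0.16. Expression filtering by group (filterByExpr) kept 17344 genes, library scaling used trimmed means of M values (TMM), and a quasi-likelihood model with 1 mean per group was fitted to all 9 libraries, so that the 3 groups shared the estimate of the spread. The comparisons were untreated against normal, SOT against untreated and SOT against normal. Genes with a Benjamini-Hochberg adjusted p under 0.05 are described as having risen or fallen. Levels are TMM-normalised CPM as the mean and SD of 3 libraries. The test, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, with the count model chosen in advance for the case that the table held counts.

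The 29 gene lists covered fibrillar matrix; elastic fibre, hyaluronan and small proteoglycans; TGF-beta and myofibroblast genes; matrix proteolysis; inflammatory cytokines and chemokines; interferon response; antioxidant and NRF2 target genes; production of reactive oxygen species; and markers of macrophages, neutrophils, T and NK cells, B and plasma cells, mast cells and endothelium. They also covered angiogenic factors, stratified epithelium, airway secretory and ciliated epithelium, skeletal muscle, muscle regeneration, cartilage, adipocytes, nerve and Schwann cells, erythrocytes, proliferation, oxidative phosphorylation, hypoxia and glycolysis, endoplasmic reticulum stress, immediate early genes, and ferroptosis with lipid peroxidation. Each list was tested against the other genes with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Counts given "within the list" rest on p adjusted over the tested genes of that list alone. Each list was tested again with an estimated correlation, and with fry, which tests whether a list's genes move on balance in 1 direction. Per library, a list score was the mean log2 CPM of its genes minus the mean of the normal libraries.

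Named genes followed a rule with 3 parts. The first part took, per comparison, the 6 genes with a symbol that rose most and the 6 that fell most among genes that passed and whose values in the groups did not overlap, or, where none passed, the 4 with the smallest p in each direction. The second took up to 4 members of each list with the largest change among those that passed, or the 2 with the smallest p where none passed. The third took 27 genes of inflammation, scarring, oxidative stress and epithelium fixed in advance, of which 26 were tested and MYH2 was not in the table. The 2 genes without a symbol that passed in SOT against untreated fall outside the rule and were chosen after their values were seen.

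Alternatives were median-ratio scaling, no expression filter, a stricter filter of FPKM of at least 5 in 3 libraries, the replicate number as a block, only the 6 libraries compared, DESeq2 1.42.0, a threshold of 2-fold or more, and leaving out each of the 9 libraries in turn. The deposited FPKM values were also tested with limma on 13798 genes with FPKM of at least 1 in 3 libraries. That test was run with pseudocounts of 1, 0.5 and 0.1, without the filter, rescaled to TPM, with median-ratio scaling, with quantile normalization, with weights per library and with the block. Other splits of the libraries were counted with the same test, 10 for each comparison and 100 assignments of the 9 libraries to 3 groups.

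The tests were tried on simulated data in which 100 genes per fold size were changed among 17344 genes. Of genes changed 2-fold and 4-fold, 21% and 64% were recovered in untreated against normal, with 4 false calls. In SOT against untreated these were 25% and 61% with 2, and in SOT against normal 16% and 71% with 4. With macrophage genes 2-fold lower in SOT against untreated, camera gave adjusted p = 2.52e-43 (0.000136 with an estimated correlation) and called 0 other lists. Other splits of the real libraries called 12 to 17, so 0 is no baseline. Annotation terms (KEGG, from the deposited table) were tested with the hypergeometric test for 310 terms with at least 10 of the 7306 tested genes that carried a term. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library and no column of values was left out.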

Results

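Transcript levels were measured in 9 rabbit vocal fold libraries: 3 from normal folds, 3 from injured folds left untreated and 3 from injured folds given the SOT hydrogel, which the study title describes as an antioxidant and adhesive material. Injured folds were taken 1 week after injury. Total counts ranged from 44755718 to 50338111 per library, and 17344 genes were tested. Levels are normalised counts (CPM, edgeR) as mean ± SD with n = 3, and positions are those of the build OryCun2.0. Adjusted p-values are from edgeR's quasi-likelihood test unless another test is named.

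Injured untreated folds were compared with normal folds to ask which transcripts differ 1 week after injury. CD68, a lysosomal glycoprotein of macrophages on chromosome 19 at 11598423 to 11600560, rose from 34.4 ± 5.22 CPM in normal folds to 263 ± 13.3 CPM in untreated folds (log2 fold change 2.94, SE 0.14, adjusted p = 0.000177). The collagenase gene MMP1, on chromosome 1 at 113747022 to 113756573, rose from 40.1 ± 13.1 to 1130 ± 106 CPM (log2 fold change 4.82, SE 0.60, adjusted p = 0.00124). COL1A1, which encodes a chain of type I collagen on chromosome 19 at 37474894 to 37490691, rose from 1980 ± 527 to 11700 ± 187 CPM (log2 fold change 2.56, SE 0.36, adjusted p = 0.00207). ELN, which encodes elastin, fell from 750 ± 222 to 148 ± 20.1 CPM (log2 fold change -2.34, SE 0.48, adjusted p = 0.00785). Among the fixed lists, 12 of 15 cartilage, 10 of 14 nerve and 23 of 24 oxidative phosphorylation genes fell, while 3, 4 and 1 did not pass. By camera with an estimated correlation these lists had adjusted p = 0.28, 0.28 and 0.383. In all, 5692 genes passed, 3074 higher and 2618 lower in untreated folds. The larger side depended on the method, with 3555 and 3626 by DESeq2, 2649 and 2786 by limma with quantile normalization and 2905 and 2975 by limma without a filter. The count was 3418 without untreated replicate 2 and 3145 without untreated replicate 3. Of 130 named genes that passed here, 95 passed in each of the 9 fits that left out 1 library. In the text on this comparison, genes that the rule named and that are given as risen or fallen are among those 95 unless a left-out value is given.

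Of 21 measured macrophage markers, 16 rose and 5 did not pass. CLEC7A, a receptor for fungal glucans, rose from 4.56 ± 0.802 to 76.5 ± 14.9 CPM, and CD14, a co-receptor for bacterial lipopolysaccharide, from 24.2 ± 7.05 to 344 ± 42.4 CPM. The scavenger receptor gene MSR1 rose by 4.06 and ADGRE1 by 4.46 on the log2 scale. MRC1, the mannose receptor, rose from 72.7 ± 5.50 to 151 ± 8.43 CPM (adjusted p = 0.0437). This call was lost without any library of either group, with the highest adjusted p of 0.112 without normal replicate 3. Of 14 neutrophil markers, 10 rose, among them the chemokine receptors CXCR2, from 2.11 ± 0.951 to 119 ± 30.9 CPM, and CXCR1, from 7.09 ± 3.06 to 324 ± 75.5 CPM. There were 16 macrophage and 11 neutrophil markers that rose with p adjusted within the list. By camera the adjusted p was 1.96e-22 for the macrophage list (0.19 with an estimated correlation) and 2.01e-07 for the neutrophil list (adjusted p = 0.376 with an estimated correlation).

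Of 28 cytokine and chemokine genes, 20 rose. IL6 rose from 0.705 ± 0.448 to 30.8 ± 15.4 CPM, and CSF2, a growth factor for granulocytes and macrophages, was at 0 in the normal libraries and at 1.48 ± 0.189 CPM in the untreated ones, at least 22.1-fold higher. IL1B rose from 19.2 ± 11.3 to 1190 ± 73.9 CPM (adjusted p = 0.0173), with 0.0603 without normal replicate 1 and 0.0550 without normal replicate 2. TNF rose from 1.88 ± 0.404 to 76.6 ± 37.2 CPM (adjusted p = 0.0233), and its call was lost without any of normal replicates 1 (0.0798), 2 (0.0763) and 3 (0.0642) or without untreated replicate 3 (0.0561). CXCL8, a neutrophil attractant, rose from 27.4 ± 16.4 to 1440 ± 576 CPM (adjusted p = 0.0203), and its call was lost without the same libraries (0.0694, 0.0662, 0.0507 and 0.0501). The list median was 2.92 on the log2 scale, also with CSF2 at its bound. Of its genes 22 rose within the list, and camera gave an adjusted p of 2.98e-09 (adjusted p = 0.368 with an estimated correlation). Of 20 interferon response genes, 6 rose (7 within the list), among them the antiviral gene RSAD2, from 13.0 ± 3.69 to 163 ± 12.4 CPM. The interferon list had an adjusted p of 9.26e-05 by camera and 0.612 with an estimated correlation. Without normal replicate 1, 12 cytokine genes rose, and without SOT replicate 3, 16 interferon genes rose (17 within the list).

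Matrix genes rose as well. Of 24 fibrillar matrix genes, 20 rose (20 within the list): TNC, a matrix glycoprotein of healing tissue, from 61.1 ± 16.6 to 1590 ± 505 CPM, CTHRC1 from 6.04 ± 3.31 to 103 ± 10.4 CPM, and COL3A1, on chromosome 7 at 129298041 to 129341606, from 4580 ± 906 to 14800 ± 292 CPM. FN1, which encodes fibronectin, rose from 1440 ± 198 to 6110 ± 124 CPM (adjusted p = 0.0132, and 0.0513 without normal replicate 1). The ratio of COL1A1 to COL3A1 was 0.433 ± 0.095 in normal and 0.791 ± 0.016 in untreated folds (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Of 24 matrix proteolysis genes, 19 rose and 2 fell (20 and 2 within the list), with MMP9 from 2.78 ± 1.65 to 223 ± 56.1 CPM, MMP13 from 6.23 ± 4.54 to 425 ± 117 CPM and the inhibitor TIMP1 from 41.1 ± 16.8 to 280 ± 46.7 CPM. Camera gave an adjusted p of 3.35e-14 for fibrillar matrix and 1.93e-13 for proteolysis (adjusted p = 0.286 and 0.28 with an estimated correlation).

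Of 21 TGF-beta and myofibroblast genes, 11 rose and 2 fell (14 and 3 within the list). TGFB1 rose from 12.4 ± 1.47 to 45.8 ± 4.31 CPM. ACTA2, the smooth muscle actin of myofibroblasts, did not pass, with 250 ± 73.1 and 497 ± 111 CPM (adjusted p = 0.136, and 0.0306 without SOT replicate 3). The list had an adjusted p of 0.000733 by camera and 0.486 with an estimated correlation. Elastic fibre, hyaluronan and small proteoglycan genes went both ways, with 8 of 23 higher and 8 lower (8 and 8 within the list) and no call for the list (adjusted p = 0.397). ASPN, which encodes asporin, rose from 51.1 ± 12.9 to 1370 ± 215 CPM, whereas FMOD (fibromodulin) fell from 277 ± 121 to 13.4 ± 3.25 CPM and PRELP from 462 ± 175 to 43.9 ± 5.07 CPM. HAS2, a hyaluronan synthase, rose from 12.2 ± 5.11 to 49.9 ± 5.78 CPM (adjusted p = 0.0132), with 0.0524 without normal replicate 1 and 0.0501 without normal replicate 3. DCN, which encodes decorin, fell from 1900 ± 398 to 1220 ± 18.3 CPM (adjusted p = 0.0248). The decorin call was lost without any library of the pair except normal replicate 3, with the highest adjusted p of 0.0890 without untreated replicate 3. Of the TGF-beta list 7 genes rose without normal replicate 1 or untreated replicate 2, and within the list 9 rose without normal replicate 1 or 3 and 8 without untreated replicate 2 or 3. Of the proteoglycan list 4 rose without normal replicate 1.

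Genes of oxidant handling moved in both directions. Of 25 antioxidant and NRF2 target genes, 7 rose and 6 fell (7 and 7 within the list), and the list was not called (adjusted p = 0.867). HMOX1, a haem-degrading enzyme, rose from 32.8 ± 4.77 to 115 ± 11.1 CPM. SOD2, the mitochondrial superoxide dismutase, fell from 476 ± 37.4 to 210 ± 24.5 CPM and the extracellular SOD3 fell from 139 ± 68.9 to 14.7 ± 9.60 CPM. Catalase (CAT) rose from 142 ± 30.6 to 219 ± 14.7 CPM (adjusted p = 0.0264), with the call lost without normal replicate 2 (0.0726) or 3 (0.0615) or without untreated replicate 2 (0.0836) or 3 (0.0827). NQO1 had 45.6 ± 4.26 and 45.2 ± 3.38 CPM (adjusted p = 0.973). The 7 antioxidant genes that rose became 4 without normal replicate 2 or 3 or untreated replicate 1 and 3 without untreated replicate 2 or 3, and within the list 4 and 3 without untreated replicates 2 and 3. Of 14 genes that produce reactive oxygen species, 7 rose and 1 fell (7 and 2 within the list). They include CYBB, the catalytic subunit of the phagocyte oxidase on chromosome X at 23358936 to 23394566, from 9.20 ± 0.812 to 75 ± 13.1 CPM. Of 16 ferroptosis and lipid peroxidation genes, 9 rose and 1 fell (9 and 1 within the list). FTL, a ferritin chain, rose from 505 ± 64.3 to 2410 ± 169 CPM, and ALOX15, at 0 in normal folds and at least 14.0-fold higher in untreated ones. The oxidase and ferroptosis lists had adjusted p of 0.000785 and 0.000342 by camera, and 0.28 for each with an estimated correlation. The ferroptosis median of 1.02 was also 1.02 with ALOX15 at its bound.

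Cartilage, nerve and muscle genes fell (tissue content untested). Of 15 cartilage markers, 12 fell (12 within the list), with COL2A1, the collagen of cartilage, from 1850 ± 673 to 28.4 ± 16.4 CPM. Of 14 nerve and Schwann cell markers, 10 fell (11 within the list), with S100B from 275 ± 174 to 5.67 ± 3.71 CPM. Of 22 skeletal muscle markers, 12 fell (15 within the list), with the slow myosin light chain MYL3 from 52.9 ± 23.2 to 0.698 ± 0.711 CPM, and the list score was -1.43, -4.70 and -2.65 in untreated replicates 1, 2 and 3. Of 24 oxidative phosphorylation genes, 23 fell (24 within the list), with SDHA of respiratory complex II from 725 ± 60.4 to 272 ± 56.6 CPM. The muscle count rested on single libraries: 3 fell without any of normal replicates 1, 2 and 3 or untreated replicate 2, and 1 without untreated replicate 3. Within the list 3 muscle genes fell without normal replicate 1 and 1 without normal replicate 3 or untreated replicate 3. Oxidative phosphorylation scored -0.80, -1.36 and -1.22 in untreated replicates 1, 2 and 3, lowest where muscle did. Camera gave adjusted p of 1.04e-09 for cartilage, 1.14e-06 for nerve, 9.52e-07 for muscle and 7.62e-11 for oxidative phosphorylation (adjusted p = 0.28, 0.28, 0.49 and 0.383 with an estimated correlation).

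Epithelial genes showed no list call. Of 24 stratified epithelium markers, 3 rose and 2 fell (3 and 2 within the list; camera adjusted p = 0.496). The wound keratin KRT16 rose from 8.71 ± 1.25 to 365 ± 155 CPM and KRT5 from 1440 ± 502 to 4870 ± 1710 CPM. In contrast SPRR3 of the cornified envelope fell from 113 ± 58.9 to 3.37 ± 1.11 CPM. KRT13 did not pass, with 8290 ± 4840 and 3730 ± 1230 CPM (adjusted p = 0.101, and 0.0342 by DESeq2). Of 21 airway secretory and ciliated markers, 1 rose and 3 fell (1 and 3 within the list), with the mucin MUC5AC from 0.896 ± 0.263 to 19.8 ± 2.03 CPM and the water channel AQP5 from 606 ± 188 to 44.0 ± 35.5 CPM. Stratified genes that rose were 5 without normal replicate 3, and those that fell were 1 without untreated replicate 2 or 3 and 5 without SOT replicate 2, also within the list. Airway genes that fell were 5 without normal replicate 3 and 1 without untreated replicate 2 or 3. With p adjusted within the list they were 7 without normal replicate 3, 1 without untreated replicate 2 and 0 without normal replicate 1 or untreated replicate 3. The airway list was not called (adjusted p = 0.154) except without normal replicate 3 (median -1.90, adjusted p = 0.004), and normal replicates 1, 2 and 3 had airway scores of 1.32, -0.02 and -1.30.

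Of 25 proliferation genes, 22 rose (24 within the list), with the mitotic kinase AURKA from 8.26 ± 4.14 to 27.5 ± 2.48 CPM. Camera gave an adjusted p of 1.23e-08, or 0.476 with an estimated correlation. Normal replicate 3 had a proliferation score of 0.75 against -0.39 and -0.36 in normal replicates 1 and 2. MKI67 passed without it (77.3 ± 47.6 against 138 ± 9.34 CPM, adjusted p = 0.0988 with all libraries and 0.00129 without it). The 22 proliferation genes became 9 without normal replicate 2 and 10 without untreated replicate 2 or 3. Of 19 endothelial markers, 6 rose and 1 fell (6 and 1 within the list), with PECAM1 from 117 ± 21.6 to 483 ± 40.1 CPM. Of 18 angiogenic factors, 9 rose and 2 fell (9 and 2 within the list), with HIF1A from 98.1 ± 8.89 to 636 ± 104 CPM. VEGFA had 277 ± 48.1 and 244 ± 5.86 CPM (adjusted p = 0.6). Both lists had an adjusted p of 0.0267 by camera (adjusted p = 0.71 and 0.637 with an estimated correlation), and without normal replicate 3 it was 0.0736 and 0.0822. On TPM the angiogenic call was lost (0.0557). Of 17 immediate early genes, 5 rose and 1 fell (5 and 1 within the list), with ZFP36 from 48.1 ± 6.01 to 282 ± 35.2 CPM. The angiogenic genes that rose were 5 without normal replicate 1 or untreated replicate 3. Within the list, 10 endothelial genes rose without normal replicate 2 or SOT replicate 1 and 11 without SOT replicate 3, and 8 immediate early genes rose without normal replicate 2 or SOT replicate 3. The immediate early list had an adjusted p of 0.0463 (adjusted p = 0.642 with an estimated correlation), and 0.0513 and 0.167 without normal replicates 1 and 3, 0.0639 without untreated replicate 1 and 0.0595 without SOT replicate 2. With limma on log2(FPKM + 0.1) and TPM it was 0.0652 and 0.0581.

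The other lists were not called by camera. Of 20 T and NK cell markers, 1 rose and 1 fell (adjusted p = 0.867), and IL7R rose from 6.22 ± 1.54 to 23.6 ± 7.56 CPM. Of 13 B and plasma cell markers, 1 rose and 1 fell (adjusted p = 0.867), with CD22 from 3.89 ± 0.839 to 35.8 ± 0.964 CPM. Of 6 mast cell markers, 2 rose (adjusted p = 0.260), with SRGN, a proteoglycan of leukocyte granules, from 59.4 ± 20.4 to 1050 ± 81.2 CPM. Of 11 muscle regeneration genes, 2 rose (adjusted p = 0.682), the fetal acetylcholine receptor subunit CHRNG by 3.12 and the fusion factor MYMX by 3.00 on the log2 scale. Of 11 adipocyte markers, 1 rose and 3 fell (adjusted p = 0.444, median -0.16 also with LEP at its bound), with LPL from 220 ± 13.8 to 63.5 ± 12.5 CPM and ADIPOQ from 119 ± 9.75 to 281 ± 31.7 CPM. Of 25 hypoxia and glycolysis genes, 10 rose and 6 fell (adjusted p = 0.328), with the lactate exporter SLC16A3 from 8.19 ± 2.91 to 90.2 ± 13.6 CPM and ALDOC from 256 ± 203 to 13.5 ± 3.76 CPM. Of 17 endoplasmic reticulum stress genes, 5 rose (adjusted p = 0.167, and 0.0194 without normal replicate 1), with PDIA6 from 281 ± 44.8 to 572 ± 53.9 CPM. None of 5 erythrocyte markers passed (adjusted p = 0.718), but 1 rose without normal replicate 1 and 1 fell without untreated replicate 2. The T and NK cell gene and the B cell gene that fell did not pass without normal replicates 1 or 2 or any of untreated replicates 1, 2 and 3, nor the B cell gene without SOT replicate 1. Of the B cell list 3 fell without normal replicate 3, 2 without SOT replicate 2, and 2 rose and 2 fell without SOT replicate 3. Of the adipocyte list 2 rose without normal replicate 1. A mast cell gene fell without normal replicate 3, and a regeneration gene without untreated replicate 1 or SOT replicate 2. With p adjusted within the list, the counts higher and lower were 1 and 0 for T and NK cells, 1 and 0 for B cells, 2 and 1 for mast cells, 2 and 0 for muscle regeneration, 1 and 3 for adipocytes, 11 and 6 for hypoxia and 5 and 0 for endoplasmic reticulum stress. Hypoxia genes that rose were 6 without normal replicate 1 or 2 or untreated replicate 3 (7 within the list without normal replicate 1). Endoplasmic reticulum genes that rose were 1 without normal replicate 2 or 3 or untreated replicate 2 or 3. With p adjusted within the list they were 1 without normal replicate 2 or untreated replicate 2 or 3, 3 without untreated replicate 1 and 0 without normal replicate 3.

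Genes found in 1 of the groups alone stood at the ends of the list of changes. MS4A3, a marker of granulocyte and monocyte precursors, was at 0 in normal folds and at 7.22 ± 2.32 CPM in untreated folds, at least 108.0-fold higher. The homeobox gene EN1 was at least 49.8-fold, CEBPE at least 30.1-fold and CA5A at least 28.8-fold higher. IL26 was at 5.63 ± 1.56 CPM in normal folds and at 0 in untreated folds, at least 89.2-fold lower, and the cartilage gene UCMA was at least 40.5-fold and IRS4 at least 23.5-fold lower. UGT1A7, DAPL1, GRIA1 and ELFN2 also belonged to these extremes but lost the call without untreated replicate 3 (adjusted p = 0.0857, 0.0600, 0.0536 and 0.0556) and without other libraries.

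SOT-treated injured folds were compared with untreated injured folds, the contrast that addresses the hydrogel itself. Of 21 macrophage, 24 matrix proteolysis and 24 fibrillar matrix genes, 20, 21 and 24 had negative log2 fold changes, and 0 passed by edgeR. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.227, 0.459 and 0.521). CD68 had 142 ± 11.6 CPM in SOT and 263 ± 13.3 CPM in untreated folds (log2 fold change -0.89, SE 0.13, adjusted p = 0.0749), and each SOT value lay below each untreated value. The 2 genes that passed both fell and have no symbol. LOC103345297, described as linker for activation of T-cells family member 2, an adaptor of myeloid and B cell receptors, fell from 61.2 ± 7.27 to 23.1 ± 1.70 CPM (log2 fold change -1.40, SE 0.12, adjusted p = 0.0219). LOC103346274, described as CMRF35-like molecule 6, a leukocyte surface receptor with close paralogs, fell from 10.9 ± 1.53 to 1.97 ± 0.251 CPM (log2 fold change -2.47, SE 0.22, adjusted p = 0.0219). Both calls were lost without most single libraries. For LOC103345297 the adjusted p was 0.0532, 0.0592 and 0.0649 without normal replicates 1, 2 and 3, 0.0686 and 0.17 without untreated replicates 2 and 3, and 0.0902 and 0.201 without SOT replicates 2 and 3. For LOC103346274 it was 0.0532, 0.0592 and 0.0649 without the normal replicates, 0.0527, 0.0515 and 0.17 without untreated replicates 1, 2 and 3, and 0.0902 and 0.159 without SOT replicates 2 and 3. With limma on log2(FPKM + 0.1) it was 0.0738 for both.

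At an unadjusted p under 0.05 there were 2194 genes, 877 higher and 1317 lower, where 867 would be expected by chance. DESeq2 called 682 genes, 229 higher and 453 lower, and limma on log2(FPKM + 1) called 33, 8 higher and 25 lower. With pseudocounts of 0.5 and 0.1 limma called 0 (unadjusted p under 0.05 for 2492 and 2479 genes). With the stricter filter and with only the 6 libraries edgeR called 0 (1500 and 2032 genes). Of the named genes of this comparison, 41 of 87 passed by DESeq2 and 5 of 85 on TPM. Among genes described here and below as not passing by edgeR, DESeq2 called CD68 (adjusted p = 1.89e-07), CSF1R (4e-06), MMP1 (0.000767), ELN (0.00074), CAT (0.0186) and SCGB1A1 (0.000363). It also called CYBB, NOX1, FAM150B, HHIPL2, NOV, MAN2B1, SLC43A2, TFEC, EPB41L3, PRELP, TGFB1, CD8A, MS4A2, ACAN, FTL and DCN (0.0487 or less). Without SOT replicate 1, 397 genes passed, 76 higher and 321 lower, while 6 passed without untreated replicate 1, 1 without SOT replicate 2 or SOT replicate 3, and 0 by edgeR without any of the normal replicates or untreated replicates 2 and 3.

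Of 21 macrophage markers, 20 had lower levels in SOT folds and 16 fell within the list, though 0 passed over all genes. CSF1R, the receptor for macrophage growth factor, had 186 ± 34.1 against 406 ± 62.3 CPM (adjusted p = 0.0824, and 0.0231 without SOT replicate 1), and for CD68 the adjusted p was 0.0273 without SOT replicate 1. The list median was -0.94 on the log2 scale with a camera adjusted p of 1.47e-19 (adjusted p = 0.227 with an estimated correlation) and a fry adjusted p of 0.0404. The oxidase gene CYBB had 29.2 ± 6.70 against 75 ± 13.1 CPM (adjusted p = 0.0749, and 0.0143 without SOT replicate 1). NOX1, an epithelial oxidase on chromosome X at 88493924 to 88518606, had 39.2 ± 10.9 against 7.86 ± 2.59 CPM (log2 fold change 2.32, adjusted p = 0.0749, and 0.0143 without SOT replicate 1). Of 14 oxidase genes 1 rose and 4 fell within the list. Their median was -0.05 with a camera adjusted p of 0.0101 for lower levels (adjusted p = 0.459 with an estimated correlation, and 0.0565 by camera without SOT replicate 2). Without SOT replicate 1, 9 macrophage genes fell, and 1 oxidase gene rose and 4 fell, over all genes.

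Neutrophil and cytokine genes differed among the SOT libraries themselves. The neutrophil score was 3.85, 1.37 and 0.41 in SOT replicates 1, 2 and 3 against 4.08 to 4.26 in untreated folds. The cytokine score was 3.41, 1.97 and 0.95 against 2.92 to 3.47. IL1B had 500 ± 773 against 1190 ± 73.9 CPM (log2 fold change -1.26, adjusted p = 0.702), and -4.42 with an adjusted p of 0.0418 without SOT replicate 1. TNF had 59.3 ± 94.1 against 76.6 ± 37.2 CPM (adjusted p = 0.924), and a log2 fold change of -3.92 with an adjusted p of 0.0143 without that library. CXCL8 had 716 ± 1100 against 1440 ± 576 CPM (adjusted p = 0.771) and IL6 8.72 ± 9.87 against 30.8 ± 15.4 CPM (adjusted p = 0.492). Of 14 neutrophil genes 1 fell, and of 28 cytokine genes 0, within the list. Camera gave adjusted p of 3.92e-09 and 0.000601 for lower levels of the 2 lists (adjusted p = 0.459 and 0.564 with an estimated correlation). Without SOT replicate 1, 5 neutrophil and 7 cytokine genes fell over all genes, and 12 and 14 within the list.

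**Figure D1:**
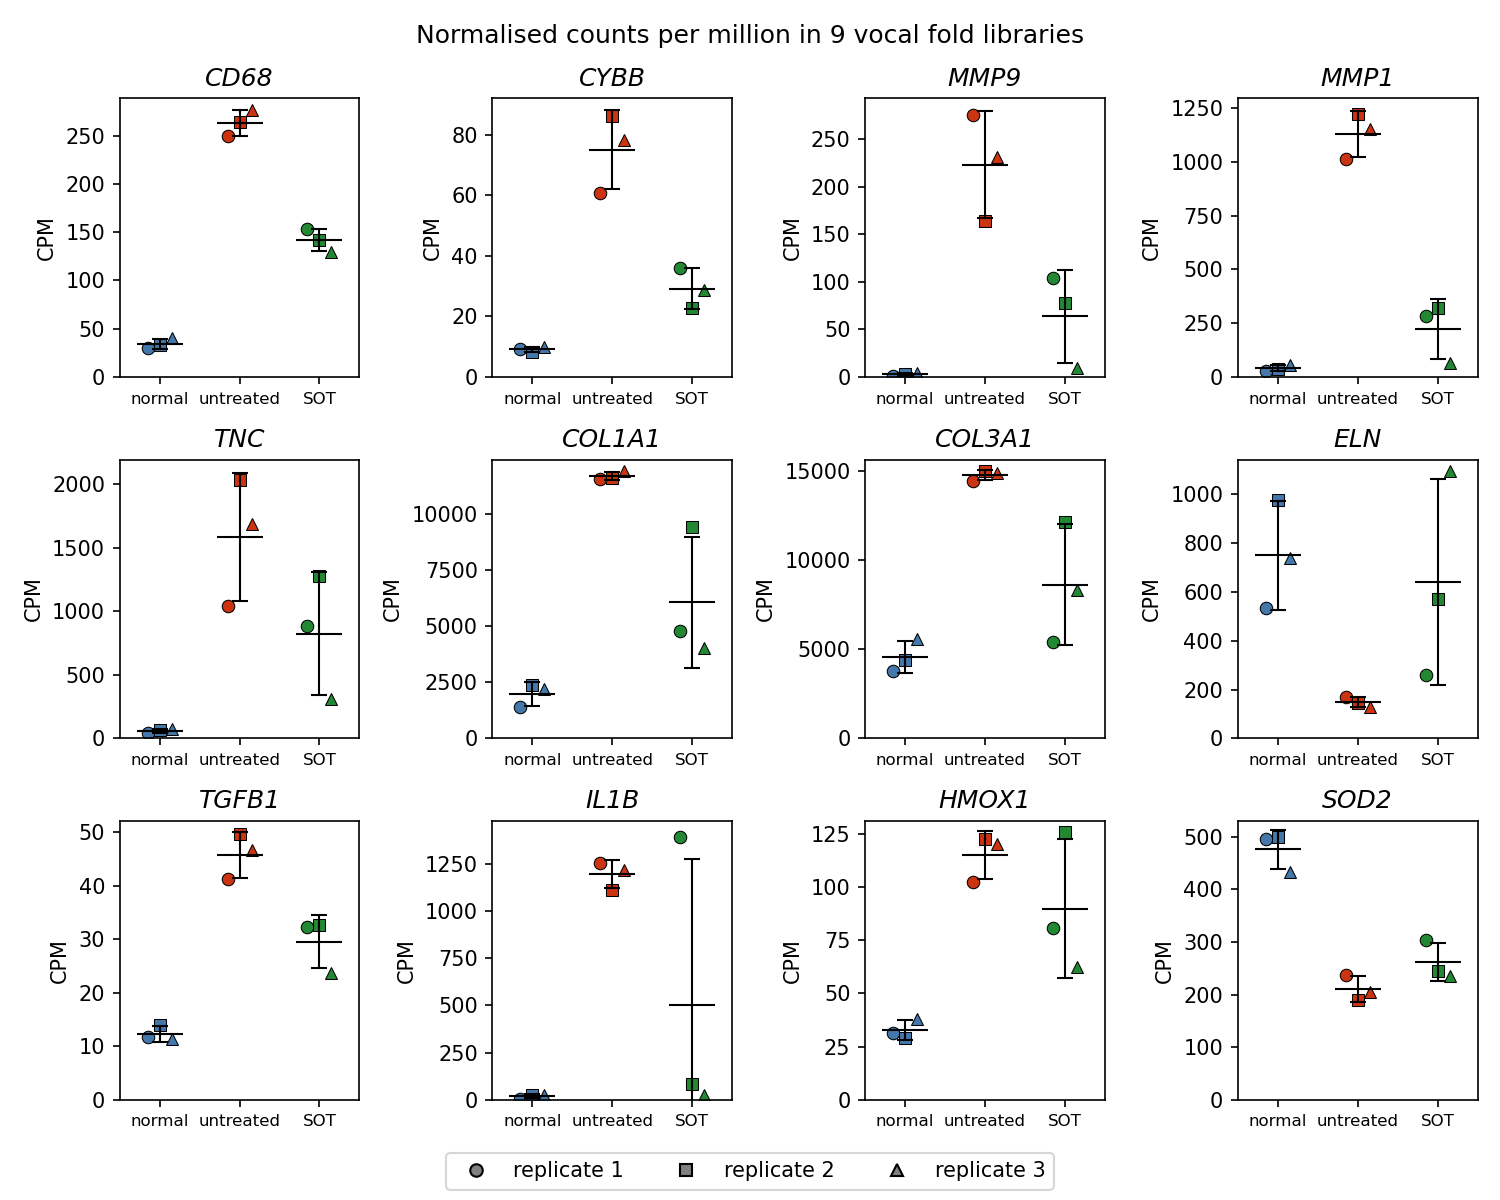
Normalised counts (CPM, vertical axes, from 0) of 12 named genes in the 9 libraries by group, with symbols for replicate numbers, a horizontal line at each group mean and bars of 1 SD. CD68 was between the groups in all SOT libraries, whereas IL1B in SOT replicate 1 was at the level of the untreated libraries.

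Matrix genes had lower mean levels in SOT folds with a wide spread. COL1A1 had 6060 ± 2920 against 11700 ± 187 CPM (log2 fold change -0.95, adjusted p = 0.318), COL3A1 8610 ± 3390 against 14800 ± 292 CPM (adjusted p = 0.337) and FN1 5370 ± 4220 against 6110 ± 124 CPM (adjusted p = 0.898). The ratio of COL1A1 to COL3A1 was 0.715 ± 0.21 (two-sided exact permutation p = 0.8 against untreated folds). All 24 fibrillar matrix genes had negative log2 fold changes, with a median of -0.52, and 0 passed within the list. MMP1 had 222 ± 139 against 1130 ± 106 CPM (log2 fold change -2.35, adjusted p = 0.173), MMP9 63.6 ± 48.5 against 223 ± 56.1 CPM (adjusted p = 0.385) and TIMP1 192 ± 145 against 280 ± 46.7 CPM (adjusted p = 0.728). In the proteolysis list 21 of 24 genes were lower, and 3 fell within the list. The latter were 0 without normal replicate 2 or any of untreated replicates 1, 2 and 3 and 7 without SOT replicate 2, while 1 passed over all genes without SOT replicate 1. Without SOT replicate 2, 15 fibrillar matrix genes fell within the list. Camera gave adjusted p of 2.04e-08 for fibrillar matrix and 6.65e-10 for proteolysis (adjusted p = 0.521 and 0.459 with an estimated correlation).

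ELN had 642 ± 422 against 148 ± 20.1 CPM (log2 fold change 2.12, adjusted p = 0.169, and 0.0182 without SOT replicate 1), and PRELP 133 ± 14.4 against 43.9 ± 5.07 CPM (adjusted p = 0.0829, and 0.0420 without SOT replicate 1). In their list of 23 elastic fibre and proteoglycan genes, 3 rose and 3 fell within the list (camera adjusted p = 0.0825, and 0.00732 without SOT replicate 3). Those that rose were 5 without SOT replicate 2. Those that fell were 0 without normal replicate 2, untreated replicates 2 or 3 or SOT replicate 3 and 1 without untreated replicate 1 or SOT replicate 2. Without SOT replicate 1, 3 rose over all genes. DCN had 831 ± 65.5 against 1220 ± 18.3 CPM (adjusted p = 0.267) and HAS2 27.0 ± 15.4 against 49.9 ± 5.78 CPM (adjusted p = 0.466). TGFB1 had 29.6 ± 5.00 against 45.8 ± 4.31 CPM (adjusted p = 0.193) and ACTA2 408 ± 244 against 497 ± 111 CPM (adjusted p = 0.837). The TGF-beta list had a camera adjusted p of 0.0101 for lower levels (adjusted p = 0.565 with an estimated correlation), and 0.0513 and 0.377 without SOT replicates 1 and 3, and 7 of its genes fell within the list without SOT replicate 2. NOV (CCN family), FAM150B and HHIPL2 had the smallest p among genes at higher levels beside NOX1, each with an adjusted p of 0.0749 and log2 fold changes of 1.59, 2.63 and 2.57. The lysosomal mannosidase gene MAN2B1, SLC43A2, TFEC and EPB41L3 had the smallest p among genes with a symbol at lower levels, also with 0.0749. All of these 7 passed without SOT replicate 1 (adjusted p between 0.0143 and 0.0280), MAN2B1 and TFEC also without untreated replicate 1 (0.0485).

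The antioxidant list, which bears on the stated property of the hydrogel, was not called in SOT against untreated folds (16 of 25 genes higher, median 0.08, camera adjusted p = 0.346, 0 within the list). Without SOT replicate 1, 5 of its genes rose and 3 fell within the list. HMOX1 had 89.7 ± 32.6 against 115 ± 11.1 CPM (adjusted p = 0.577), SOD2 261 ± 36.3 against 210 ± 24.5 CPM (adjusted p = 0.411), NQO1 48.6 ± 19.5 against 45.2 ± 3.38 CPM (adjusted p = 0.887) and CAT 134 ± 18.4 against 219 ± 14.7 CPM (adjusted p = 0.189). The ferroptosis list was lower, with 4 of 16 genes falling within the list and a camera adjusted p of 0.00023 (adjusted p = 0.317 with an estimated correlation). The 4 became 2 without normal replicate 2, 0 without normal replicate 3, any of untreated replicates 1, 2 and 3 or SOT replicate 3, and 8 without SOT replicate 1, when 4 also fell over all genes. FTL had 1350 ± 368 against 2410 ± 169 CPM (adjusted p = 0.210). VEGFA had 249 ± 85.4 against 244 ± 5.86 CPM (adjusted p = 0.970), KRT5 3590 ± 1100 against 4870 ± 1710 CPM (adjusted p = 0.660), KRT13 4590 ± 2140 against 3730 ± 1230 CPM (adjusted p = 0.833) and MKI67 112 ± 5.67 against 138 ± 9.34 CPM (adjusted p = 0.746). MRC1 had 74.9 ± 43.8 against 151 ± 8.43 CPM (adjusted p = 0.287, and 0.00914 without SOT replicate 1).

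SOT replicate 3 stood apart in lymphocyte and interferon genes. Its T and NK cell score was 2.13 against 0.36 and -0.25 in SOT replicates 1 and 2, its B cell score 0.96 against -0.24 and -1.05, and its interferon score 2.47 against 1.13 and 0.76. The T and NK cell list was higher in SOT folds (19 of 20 genes with positive log2 fold changes, 0 within the list and 6 without SOT replicate 2, median 1.19, camera adjusted p = 0.000197, adjusted p = 0.564 with an estimated correlation), with 0.25 and an adjusted p of 0.365 without that library. That call was lost with limma on log2(FPKM + 0.1) and TPM (0.115 and 0.11). CD8A had 6.06 ± 4.94 against 1.15 ± 0.478 CPM (adjusted p = 0.193). The interferon list had a median of 0.54 (camera adjusted p = 0.0825), which turned to -0.17 (adjusted p = 0.0118) without SOT replicate 3 and was 0.80 (0.0132) and 0.77 (0.000249) without SOT replicates 1 and 2. The B cell list was not called (adjusted p = 0.318) except without SOT replicate 2 (median 1.13, adjusted p = 0.0155).

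Muscle, cartilage and airway lists had higher levels in SOT folds by camera: skeletal muscle with a median of 0.71 (adjusted p = 0.0032), muscle regeneration 0.97 (0.000261), cartilage 0.53 (0.0154), airway epithelium 0.91 (0.000651) and oxidative phosphorylation 0.12 (0.0188). With an estimated correlation these were adjusted p = 0.611, 0.564, 0.58, 0.564 and 0.641. The muscle score was -1.60, -3.62 and -1.51 in SOT replicates 1, 2 and 3, inside the range of untreated folds. The muscle call was lost without untreated replicate 2 (0.991), SOT replicate 1 (0.133) or SOT replicate 3 (0.167), the regeneration call without SOT replicate 1 (0.0513), and the cartilage call without untreated replicate 3 (0.0870) or SOT replicate 3 (0.340). The oxidative phosphorylation call was lost without untreated replicates 2 (0.232) and 3 (0.0819) and SOT replicates 1 (0.277) and 3 (0.167). On log2(FPKM + 0.1) the muscle, cartilage and airway calls were lost (0.134, 0.115 and 0.478), as on TPM (0.11, 0.11 and 0.444). In these lists 0 genes passed within the list. Without SOT replicate 2, 7 regeneration and 6 cartilage genes rose in this way, and without untreated replicate 1, 5 muscle genes. Of their genes, the club cell gene SCGB1A1 had 91.5 ± 77.0 against 5.01 ± 2.92 CPM (adjusted p = 0.211), ACAN 59.8 ± 49.9 against 15.0 ± 7.25 CPM (adjusted p = 0.270) and the embryonic myosin MYH3 486 ± 250 against 182 ± 130 CPM (adjusted p = 0.342).

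Hypoxia and glycolysis genes had a median of -0.44 in SOT against untreated folds (camera adjusted p = 4.55e-05), mast cell markers -0.93 (0.00419), erythrocyte markers -1.34 (0.00751), proliferation -0.34 (0.00597), angiogenic factors -0.32 (0.00659), endothelial markers -0.28 (0.00683) and endoplasmic reticulum stress -0.19 (0.0307). With an estimated correlation the adjusted p were 0.531, 0.317, 0.459, 0.611, 0.564, 0.582 and 0.611. Without SOT replicate 3 the angiogenic (0.238), endothelial (0.454), endoplasmic reticulum (0.481) and erythrocyte (0.167) calls were lost. The endoplasmic reticulum call was also lost without untreated replicate 2 (0.174), and the erythrocyte call without normal replicate 3 (0.0511), untreated replicates 1 (0.0549) and 2 (0.314) or SOT replicate 2 (0.256). PGK1 of glycolysis had 416 ± 107 against 614 ± 51.0 CPM (adjusted p = 0.287, and 0.0387 without SOT replicate 1) and the mast cell receptor chain MS4A2 2.02 ± 0.215 against 6.92 ± 0.899 CPM (adjusted p = 0.166). A mast cell gene and an erythrocyte gene fell within the list, and 0 genes passed so in the other lists of this paragraph. Without SOT replicate 1, 15 hypoxia genes fell within the list and 3 over all genes, and without SOT replicate 2, 3 angiogenic genes fell within the list. Nerve genes (median 0.38, or 0.58 with genes at 0 at their bound, adjusted p = 0.250), immediate early genes (0.222), stratified epithelium (0.708) and adipocyte genes (0.197) were not called. Without SOT replicate 2 the nerve list (0.0137) and the immediate early list (0.0163) were called. On log2(FPKM + 0.1) and TPM the immediate early list (0.0229 and 0.0196) and the adipocyte list (0.00709 and 0.00694) were called. The adipocyte list had a median of -0.09, a mean of 0.27 and a camera direction that was lower.

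**Figure D2:**
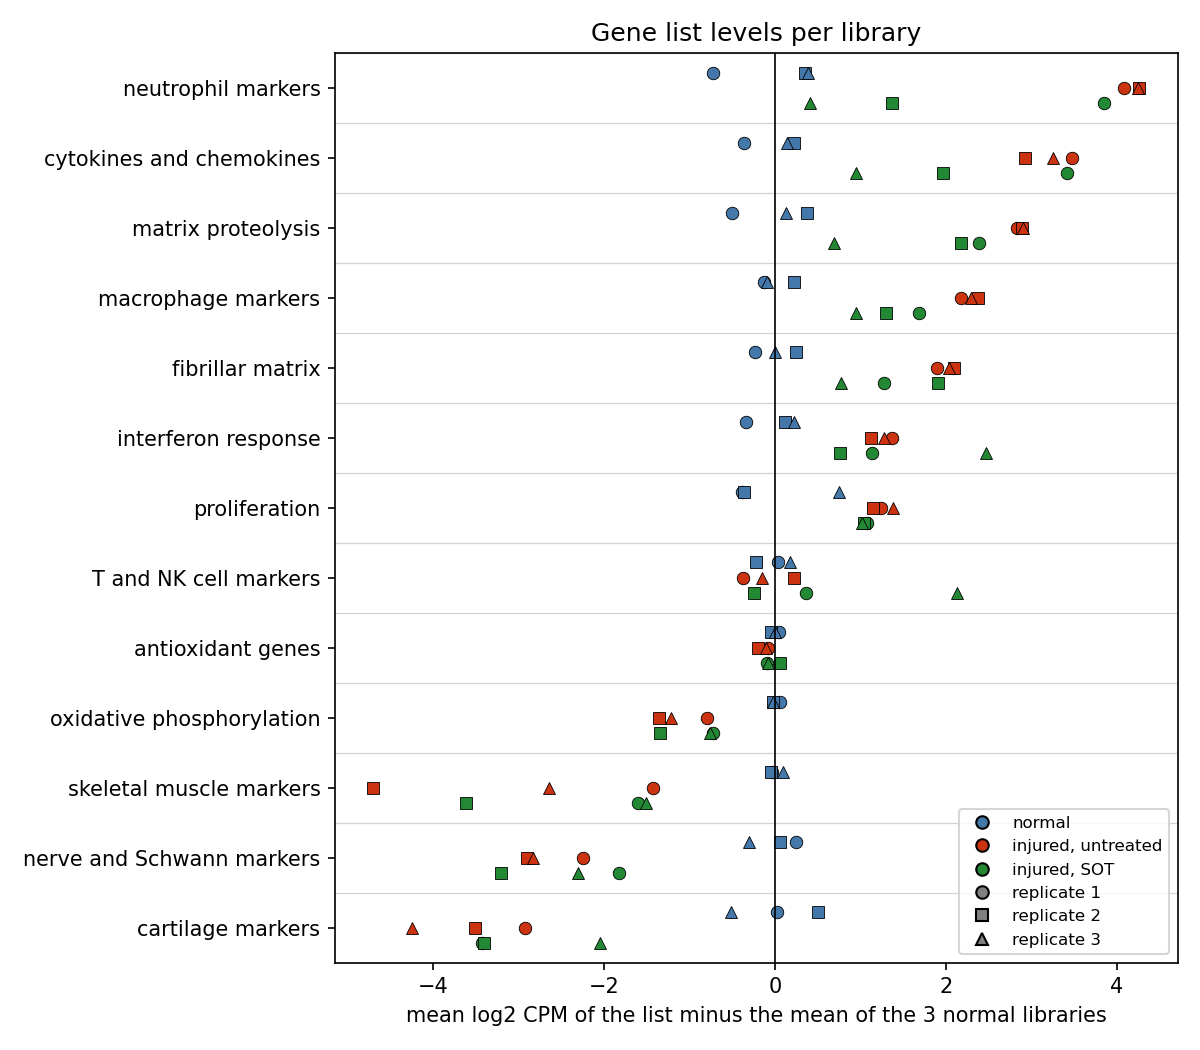
Mean log2 CPM of the genes of 13 lists in each library minus the mean of the 3 normal libraries (horizontal axis), with colours for groups and symbols for replicate numbers. Neutrophil scores spread from 0.41 to 3.85 among the SOT libraries, and SOT replicate 3 had the highest interferon (2.47) and T and NK cell (2.13) scores.

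Genes called with injury were then asked whether they moved back with SOT. The 2 genes called in opposite directions were LOC103345297 and LOC103346274, which rose with injury and fell with SOT, where 0.354 would be expected of independent lists. Unchanged groups that share the untreated libraries gave 0 in 30 simulations, but these left out the injury effect, so that value is no baseline for the count. In 30 simulations added after the data were seen, the injury difference was kept (5450 calls on average) and SOT was set equal to untreated. These gave a mean of 0.0333 opposite calls and at most 1. The real count was 344 without SOT replicate 1, 6 without untreated replicate 1 and 0 by edgeR without any other library. Across genes, which are not independent replicates, log2 fold changes of the 2 comparisons had r = -0.60. The simulated -0.50 (-0.53 to -0.45) without effects is no baseline either. The covariance was -0.714, against -0.177 without effects and -0.18 with injury kept. The 3 untreated libraries cannot be split into parts of at least 2, so part of the excess in calls may come from the shared libraries.

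SOT-treated folds were last compared with normal folds, to ask what still differed from uninjured tissue. CD68 rose to 142 ± 11.6 CPM from 34.4 ± 5.22 CPM (log2 fold change 2.04, SE 0.13, adjusted p = 0.00249) and CYBB to 29.2 ± 6.70 CPM from 9.20 ± 0.812 CPM. CTHRC1 rose to 96.6 ± 22.6 CPM and TNC to 825 ± 486 CPM, while HAPLN1 fell from 196 ± 47.9 to 35.9 ± 17.1 CPM. TGFB1 rose to 29.6 ± 5.00 CPM and SOD2 fell to 261 ± 36.3 CPM. ELN did not pass, with 642 ± 422 against 750 ± 222 CPM (log2 fold change -0.23, adjusted p = 0.774).

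In all, 2894 genes passed, 1563 higher and 1331 lower in SOT folds. The share of higher genes, 54%, moved in both directions with the method. By limma on log2(FPKM + 1) 2315 were higher and 1286 lower (64.3%), and on TPM the share was 66.4%. With only the 6 libraries 692 were higher and 886 lower (43.9%), with median-ratio scaled FPKM 1479 and 1639 (47.4%), and with quantile normalization 49.1%. The count was 1135 without normal replicate 1, 1442 without normal replicate 2, 1680 without SOT replicate 2 and 1783 without untreated replicate 3. Of 112 named genes that passed, 47 passed in each of the 9 fits, and genes named here as risen or fallen are among them unless a left-out value is given. Genes called against normal overlapped between untreated and SOT folds: 2631 were called in both, all in the same direction, 3061 with untreated folds alone and 263 with SOT folds alone, which does not test a difference between them.

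Of 21 macrophage markers, 14 rose (15 rose and 1 fell within the list), with CLEC7A to 30.9 ± 11.1 CPM from 4.56 ± 0.802 CPM and GPNMB to 126 ± 38.9 CPM from 20 ± 2.45 CPM. MRC1 had 74.9 ± 43.8 and 72.7 ± 5.50 CPM (adjusted p = 0.947), and a log2 fold change of -0.52 (0.0478) without SOT replicate 1 where it was 0.04 with it. Of 14 oxidase genes, 7 rose (7 rose and 1 fell within the list), with RAC2 to 84.9 ± 19.8 CPM from 26.2 ± 3.73 CPM. Of 14 neutrophil markers 6 rose, and of 28 cytokine genes 16 rose (9 and 23 within the list). CSF2 was at 0 in normal folds and at least 10.4-fold higher in SOT folds, with a cytokine list median of 2.44 also with CSF2 at its bound. IL1B (adjusted p = 0.0529, and 0.0188 without SOT replicate 3), CXCL8 (0.0545 and 0.0189) and IL6 (0.0588 and 0.0130) did not pass with all libraries by edgeR, while CXCL8 and IL6 did by DESeq2 (0.000469 and 0.00119). The 6 neutrophil genes became 1 without normal replicate 1 or 2 or untreated replicate 3 and 3 without normal replicate 3. The 16 cytokine genes became 2 without normal replicate 1 or 2, 5 without normal replicate 3 and 8 without untreated replicate 3. Within the list, 1 neutrophil and 13 cytokine genes rose without normal replicate 1, and the oxidase genes that rose over all genes were 3 and 2 without normal replicates 1 and 2. TNF passed (adjusted p = 0.0464) but not without any library other than SOT replicates 2 and 3 (highest 0.139 without normal replicate 1, and 0.0567 without SOT replicate 1). With limma on log2(FPKM + 0.1) and TPM TNF had 0.0885 and 0.097.

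Of 20 interferon genes, 14 rose (19 within the list), with RSAD2 to 71.9 ± 42.7 CPM from 13.0 ± 3.69 CPM (adjusted p = 0.0128, and 0.0524 without normal replicate 1). The 14 interferon genes became 1, 5 and 7 without normal replicates 1, 2 and 3 and 7, 7 and 6 without untreated replicates 1, 2 and 3. Camera gave adjusted p of 4.96e-14 for macrophage, 0.00292 for oxidase, 0.000431 for neutrophil, 5.6e-09 for cytokine and 8.9e-10 for interferon lists, and 0.264, 0.389, 0.523, 0.389 and 0.424 with an estimated correlation. The oxidase call was lost without SOT replicate 3 (0.0868) and with limma on log2(FPKM + 0.1) and TPM (0.145 and 0.143). The T and NK cell list was higher (20 of 20 genes with positive log2 fold changes, median 1.02, adjusted p = 0.0349, adjusted p = 0.8 with an estimated correlation), with a median of 0.01 (0.962) without SOT replicate 3 and 0.0559 without normal replicate 3. On log2(FPKM + 0.1) and TPM it was 0.257 and 0.244. CD22 rose to 22.5 ± 3.66 CPM from 3.89 ± 0.839 CPM in a B cell list that was not called (adjusted p = 0.799), with a median of -0.33, a mean of 0.01 and a higher camera direction. The mast cell list was not called either (adjusted p = 0.981), with 1 of 6 genes higher, a median of -0.28, a mean of 0.23 and a lower camera direction. With p adjusted within the list, 0 T and NK cell (4 without SOT replicate 2), 1 B cell and 1 mast cell gene rose.

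Of 24 fibrillar matrix genes, 13 rose (17 within the list). COL1A1 rose to 6060 ± 2920 CPM from 1980 ± 527 CPM (log2 fold change 1.61, adjusted p = 0.0198, and 0.0681 without normal replicate 1), and COL3A1 had 8610 ± 3390 against 4580 ± 906 CPM (adjusted p = 0.0729, 0.0290 without SOT replicate 1 and 0.0125 by DESeq2). The ratio of COL1A1 to COL3A1 was not separated from that of normal folds (two-sided exact permutation p = 0.2). FN1 rose to 5370 ± 4220 CPM (adjusted p = 0.0325), with the highest adjusted p of 0.107 without normal replicate 1 and the call also lost without normal replicates 2 and 3 and untreated replicates 2 and 3 (0.0932, 0.0686, 0.0501 and 0.0611). Of 24 proteolysis genes, 15 rose and 2 fell (20 and 2 within the list), with ADAM12 to 98.3 ± 69.8 CPM from 5.60 ± 2.88 CPM and MMP12 to 159 ± 119 CPM from 7.07 ± 3.07 CPM. MMP1 rose to 222 ± 139 CPM (adjusted p = 0.0199; 0.0751, 0.0686 and 0.0537 without normal replicates 1 and 2 and SOT replicate 2), and MMP9 to 63.6 ± 48.5 CPM (0.0139, and 0.0501 without normal replicate 2). TIMP1 rose to 192 ± 145 CPM (adjusted p = 0.0403), with overlapping values in the groups and a call kept, of the left-out fits, only without SOT replicate 3, with the highest value of 0.129 without normal replicate 1. Camera gave adjusted p of 5.52e-11 for fibrillar matrix and 3.25e-10 for proteolysis (adjusted p = 0.389 for each with an estimated correlation). The 13 fibrillar genes became 7 without normal replicate 1 and 8 without normal replicate 2 or 3 or untreated replicate 3, and the 15 proteolysis genes 7 without normal replicate 1 or 2.

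Of 21 TGF-beta and myofibroblast genes, 5 rose and 1 fell (9 and 1 within the list; camera adjusted p = 0.00389, or 0.0648 without SOT replicate 2, and adjusted p = 0.523 with an estimated correlation). TGFBI rose to 728 ± 300 CPM from 181 ± 34.0 CPM, TPM2 fell from 3540 ± 270 to 945 ± 325 CPM, and ACTA2 did not pass (adjusted p = 0.325, and 0.0411 without SOT replicate 3). The elastic fibre and proteoglycan list was not called (adjusted p = 0.773). In it 4 of 23 genes rose and 6 fell (5 and 6 within the list). Its median was 0.14 and its mean 0.09, while its camera direction was lower. ASPN rose to 667 ± 240 CPM from 51.1 ± 12.9 CPM, MFAP5 fell from 923 ± 110 to 179 ± 74.8 CPM, and DCN fell from 1900 ± 398 to 831 ± 65.5 CPM. HAS2 did not pass (adjusted p = 0.123, and 0.0191 without SOT replicate 3). TGF-beta genes that rose were 3 without normal replicate 1 or 3 and 12 without SOT replicate 3. Within the list they were 5 without normal replicate 1 or 3 or SOT replicate 2 and 14 without SOT replicate 3. Proteoglycan genes that rose were 2 without normal replicate 1.

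Of 25 antioxidant genes, 5 rose and 4 fell (7 and 6 within the list), and the list was not called (adjusted p = 0.799). The 5 that rose became 2 without normal replicate 1 or any of untreated replicates 1, 2 and 3, 1 without normal replicate 2 or SOT replicate 2, and 8 without SOT replicate 3. The 4 that fell became 1 without normal replicate 1 or 2 or SOT replicate 2 and 2 without untreated replicate 3. Within the list, 3, 1 and 4 rose without normal replicates 1 and 2 and SOT replicate 2, and 3 fell without each of these. HMOX1 rose to 89.7 ± 32.6 CPM from 32.8 ± 4.77 CPM, while NQO1 and CAT did not pass (adjusted p = 0.833 and 0.768). Of 16 ferroptosis genes, 4 rose (5 within the list), with FTL to 1350 ± 368 CPM from 505 ± 64.3 CPM. The ferroptosis median was 0.49, or 0.43 with ALOX15 at its bound, with a camera adjusted p of 0.0173 (adjusted p = 0.424 with an estimated correlation) and 0.185 without SOT replicate 1. That call was lost on log2(FPKM + 0.1) and TPM too (0.177 and 0.155). Ferroptosis genes that rose were 2 without normal replicate 1 or 2 or SOT replicate 2 and 8 without SOT replicate 3. Within the list they were 3 without normal replicate 1 and 9 without SOT replicate 3.

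Of 15 cartilage markers, 12 fell (13 within the list), with COL2A1 from 1850 ± 673 to 105 ± 128 CPM (adjusted p = 0.0245; 0.0615, 0.0648 and 0.0568 without normal replicates 1 and 2 and SOT replicate 1). Of 14 nerve markers, 9 fell (10 within the list), with the myelin-associated gene NCMAP from 28.7 ± 11.7 to 3.64 ± 2.22 CPM. The nerve median was -2.09, also with MAG at its bound. Of 24 oxidative phosphorylation genes, 19 fell (22 within the list), with SDHA from 725 ± 60.4 to 270 ± 68.6 CPM and NDUFS1 from 261 ± 6.55 to 130 ± 26.5 CPM. Of 22 muscle markers 3 fell (5 within the list), with MYL3 from 52.9 ± 23.2 to 2.32 ± 1.24 CPM. Both lists had their lowest SOT score in SOT replicate 2 (-1.35 and -3.62). Camera gave adjusted p of 4.02e-12, 6.98e-09, 2.52e-12 and 2.33e-06 for the cartilage, nerve, oxidative phosphorylation and muscle lists (adjusted p = 0.293, 0.264, 0.389 and 0.523 with an estimated correlation). The cartilage count was 5, 3 and 7 without normal replicates 1 and 2 and SOT replicate 2, and the nerve count 5, 4 and 5 without normal replicates 1 and 2 and SOT replicate 3. Oxidative phosphorylation genes that fell were 8 without normal replicate 1 and 12 without SOT replicate 2. Muscle genes that fell were 7 without untreated replicate 2 and 1 without any of normal replicates 1, 2 and 3, untreated replicate 3 or SOT replicates 1 and 2. Within the list the muscle count was 12 and 15 without untreated replicates 1 and 2 and 1 without any of the other 7 libraries. CHRNG rose to 61.0 ± 33.5 CPM from 3.42 ± 1.07 CPM and MYMX to 10.4 ± 6.75 CPM from 0.590 ± 0.295 CPM, among 3 of 11 muscle regeneration genes that rose (3 within the list, and 7 without SOT replicate 2). The regeneration list had an adjusted p of 0.00731 (adjusted p = 0.639 with an estimated correlation) and 0.0584 and 0.0752 without SOT replicates 1 and 3. On log2(FPKM + 0.1) and TPM the regeneration list had 0.135 and 0.123.

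Of 25 proliferation genes, 7 rose (20 within the list), with AURKA to 21.4 ± 1.31 CPM from 8.26 ± 4.14 CPM (adjusted p = 0.0200, and 0.0727 and 0.0533 without normal replicates 1 and 2). Camera gave an adjusted p of 7.48e-09 (adjusted p = 0.47 with an estimated correlation). The 7 proliferation genes became 0, 1 and 21 without normal replicates 1, 2 and 3, 3, 3 and 2 without untreated replicates 1, 2 and 3, and 2, 3 and 4 without SOT replicates 1, 2 and 3. Within the list, 0 rose by edgeR without normal replicate 1 or 2, 12 without untreated replicate 3, and 10 and 5 without SOT replicates 1 and 2. MKI67 did not pass (adjusted p = 0.326) except without normal replicate 3 (0.00597). Among stratified epithelium markers 3 of 24 rose and 2 fell (adjusted p = 0.308, and 0.0251 without normal replicate 2), with the cornified envelope genes CRNN from 250 ± 209 to 15.2 ± 12.5 CPM and SPRR3 from 113 ± 58.9 to 8.52 ± 4.29 CPM. KRT5 rose to 3590 ± 1100 CPM (adjusted p = 0.0464, with the highest value of 0.137 without normal replicate 1 and the call kept, of the left-out fits, only without normal replicate 3, untreated replicate 1 and SOT replicate 3), and KRT13 did not pass (0.254). MUC5AC rose to 10.2 ± 7.53 CPM from 0.896 ± 0.263 CPM in an airway list that was not called (adjusted p = 0.906), with a median of -0.03, a mean of -0.15 and a higher camera direction. Without normal replicate 1 or 2, 0 stratified genes rose by edgeR over all genes. Of the stratified genes 3 rose and 3 fell, and of the airway genes 1 rose and 2 fell, within the list.

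Of 19 endothelial markers 3 rose and 1 fell, with KDR to 56.9 ± 12.2 CPM from 30.3 ± 4.39 CPM (list adjusted p = 0.238; 0.0401 without normal replicate 2 and 0.00691 without SOT replicate 3). Of 18 angiogenic factors 4 rose and 1 fell, with VEGFC to 21.7 ± 8.93 CPM from 7.84 ± 0.368 CPM (list adjusted p = 0.257, and 0.00151 without SOT replicate 3), and VEGFA did not pass (0.711). Of 11 adipocyte markers 1 rose and 2 fell, with LPL from 220 ± 13.8 to 40.1 ± 9.48 CPM and ADIPOQ to 288 ± 103 CPM (list adjusted p = 0.0594; 0.0303, 0.0274 and 0.0410 without normal replicates 2 and 3 and SOT replicate 1; 0.0409 and 0.0405 on log2(FPKM + 0.1) and TPM). Of 25 hypoxia and glycolysis genes 2 rose and 5 fell, with GAPDH from 1610 ± 110 to 619 ± 170 CPM and ALDOA from 4730 ± 115 to 1150 ± 356 CPM. That list was not called (adjusted p = 0.334, and 0.0234 without SOT replicate 1), with a median of 0.02, a mean of -0.18 and a lower camera direction. Immediate early genes (3 of 17 higher, adjusted p = 0.0583; 0.00795 without normal replicate 2 and 0.000108 without SOT replicate 3), endoplasmic reticulum stress (1 of 17 higher, 0.620) and erythrocyte markers (0.308) were not called. With p adjusted within the list, the counts higher and lower were 4 and 1 for endothelial, 6 and 1 for angiogenic, 1 and 2 for adipocyte, 6 and 7 for hypoxia and 3 and 0 for immediate early genes, and 0 for the other 2 lists. Without normal replicates 1, 2 and 3, 1, 0 and 2 hypoxia genes rose in this way, and 2 and 3 without SOT replicates 1 and 2, while 4 fell without normal replicate 2. Without any of normal replicates 1, 2 and 3 or SOT replicates 1 and 2, 3 angiogenic genes rose so. Endothelial genes that rose so were 1, 0 and 0 without normal replicates 1 and 3 and SOT replicate 2 and 10 without SOT replicate 3. Over all genes, 2 angiogenic genes rose and 3 hypoxia genes fell without normal replicate 1, 3 hypoxia genes fell also without normal replicate 2, and 7 hypoxia, 6 endothelial and 6 immediate early genes rose without SOT replicate 3.

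At the ends of the list of changes, BBOX1 was at 0 in normal folds and at 1.56 ± 0.747 CPM in SOT folds, at least 23.3-fold higher, and EN1 was at least 14.8-fold higher. SPOCD1 was at least 12-fold and MFRP at least 9.68-fold lower, each at 0 in SOT folds. CEBPE, PRPH, ANGPTL5, MAG, PHACTR3 and NECAB1 were at 0 in 1 of the groups too, and MSMB had 25.3 ± 29.2 against 0.051 ± 0.0883 CPM. These 7 lost the call without normal replicate 1 (adjusted p = 0.0638, 0.103, 0.0641, 0.0961, 0.0791, 0.0943 and 0.0522) and all but MSMB without other libraries as well. The CEBPE call was also lost on TPM (0.0948).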

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

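The alternatives were planned before the data were examined. In untreated against normal the 5692 calls stayed within 1.5 times under the other scalings, filters, tests and the replicate block (5526). They gave 3227 at 2-fold or more, and ranged from 3145 to 6026 when 1 library was left out. In SOT against normal the 2894 calls fell to 1578 with only the 6 libraries compared and to 1694 at 2-fold or more. They rose to 4809 with DESeq2, were 2625 with the replicate block (1236 higher and 1389 lower, or 47.1% higher), and ranged from 1135 to 3222 with 1 library left out. The 2 calls of SOT against untreated became 0 with edgeR under the stricter filter, with only the 6 libraries, and with the replicate block (unadjusted p under 0.05 for 1500, 2032 and 2159 genes). They became 0 with limma on log2(FPKM + 0.5), on log2(FPKM + 0.1) and with the block (2492, 2479 and 2524 genes). Limma gave 33 on log2(FPKM + 1), 18 without a filter, 18 on TPM, 56 with median-ratio scaling, 46 with quantile normalization and 535 with weights per library. DESeq2 gave 682, and edgeR had a range from 0 to 397 when 1 library was left out. The 2 genes that moved back with SOT became 0 with the replicate block and with limma on log2(FPKM + 0.1), and ranged from 0 to 344 with 1 library left out. Lists called by camera (17, 21 and 16 of 29) ranged from 15 to 17, from 14 to 23 and from 15 to 20 with 1 library left out, and 0 were called in each comparison with an estimated correlation, where fry called 15, 1 and 10. Without SOT replicate 3 the median fold change of the interferon list in SOT against untreated reversed (0.54 to -0.17, with a range to 0.80 over the left-out libraries). For the T and NK cell list in SOT against normal the camera direction turned lower while the median fell to 0.01 (from 1.02, range to 1.34), and MRC1 in SOT against normal reversed (0.04 to -0.52, range to 0.34) without SOT replicate 1. The cause was not tested for any of these changes. Further counts of 3 or fewer genes of a list also changed with single libraries left out. Whether replicate numbers pair samples is open. Deviations of libraries with the same number correlated between -0.06 and 0.21, and 5 of 9 correlated best with their own number. The replicate block ended the call of the angiogenic list in untreated against normal (0.0623) and called the immediate early list in SOT against normal (0.0495), and 81 named genes were called with it in SOT against normal in place of 112. In simulated data 25% of 2-fold changes were recovered in SOT against untreated, so the small count there does not show that levels were equal.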

Other observations

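The annotation terms were chosen for description after the calls had been seen, and 4 tests below were also chosen after the result: the level of lists against all genes in a library, the count of genes of untreated replicate 3 outside the range of the other untreated libraries, its residual spread, and the term test. Genes of a term are not independent, so the adjusted p of the hypergeometric test describe these calls only. Among 139 osteoclast differentiation genes, 84 rose in untreated folds (60.4%, adjusted p = 8.12e-21). In SOT folds 58 rose (7.67e-18; 26, 34 and 37 without normal replicates 1 and 2 and untreated replicate 3). Among 141 lysosome genes, 74 rose in untreated folds (adjusted p = 6.85e-14) and 43 in SOT folds (2.69e-08; 21, 27 and 27 without normal replicates 1, 2 and 3, 28 without untreated replicate 3 and 25 without SOT replicate 2), with the cathepsins CTSK at 234 ± 39.4, 1330 ± 73.1 and 761 ± 228 CPM in normal, untreated and SOT folds and CTSS at 60 ± 10.5, 412 ± 42.1 and 225 ± 46.3 CPM.

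Among 42 genes of the citrate cycle, 25 fell in untreated folds (adjusted p = 4.25e-09) and 21 in SOT folds (1.85e-10; 10, 13 and 13 without normal replicates 1 and 2 and SOT replicate 2), with MDH2 at 432 ± 21.8, 174 ± 34.9 and 195 ± 49.8 CPM. Among 68 genes that degrade branched-chain amino acids, 26 fell in untreated folds (adjusted p = 0.000182; 16 and 14 without untreated replicates 2 and 3) and 19 in SOT folds (0.000106). In SOT folds the term had 10 without normal replicate 2, and its call was lost without normal replicate 1 (7 genes, adjusted p = 0.157) or SOT replicate 2 (9 genes, 0.0637). CTSK, CTSS and MDH2 passed in untreated against normal folds in all 9 left-out fits.

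Other splits of the same 6 libraries were too few for a share under 0.05. By edgeR the real split called 5692, 2 and 2894 genes in untreated against normal, SOT against untreated and SOT against normal, where 1 of 10 splits in each (the real one) had as many and the highest other had 0, 1 and 1. Camera called 17, 21 and 16 lists against 18, 17 and 20 in the highest other, with 2, 1 and 5 of 10 splits as large, so in untreated against normal and SOT against normal, list calls at the preset correlation were as frequent in some splits that mix the groups, which in SOT against untreated they were not. Of 100 assignments of all 9 libraries to 3 groups, 4 gave 2 or more genes in opposite directions, the real one and its renaming included. The other 2 gave 2526 and 2498, with the normal libraries in the place of the group shared by the 2 comparisons and untreated and SOT libraries mixed in the other groups.

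Macrophage, matrix and protease lists were lower in SOT than in untreated libraries by camera at the preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.227, 0.521 and 0.459). More uninjured tissue like the normal libraries would move all genes back by the same share. Genes that rose at least 2-fold with injury moved back by 0.51 of the way on the linear scale and those that fell by 0.12. The difference of 0.40 (0.23, 0.53 and 0.56 by SOT replicate) argues against such tissue as the whole cause. Uninjured tissue of another make-up stays open. A scaling factor per library cancels once the median of all its genes is taken off. Macrophage, fibrillar matrix and proteolysis lists then differed by -1.06 (SE 0.20), -0.69 (0.32, nearest values -0.08 and -0.07) and -0.99 (0.53) between SOT and untreated folds. Scaling cannot make these differences, though that of proteolysis was under 2 SE and fibrillar matrix values nearly met. The planned median-ratio test (adjusted p = 1.62e-19) was void, since camera sets a list against the other genes. An effect of SOT on the entry or loss of macrophages stays open and was not tested, as does a chance difference between the samples.

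Untreated replicate 3 lay between replicates 1 and 2 for 64.8% of 4019 genes, against 27.4% to 39.1% for libraries of the other groups. Were it a mix of the other untreated libraries, the share of replicate 1 would be alike in genes high in replicate 1 or 2. The medians were 0.37 (323 genes) and 0.44 (22 genes), a difference of 0.07, inside the bound of 0.1. A log-scale midpoint would give 0.27 and 0.73. Normal replicates 1 (0.81 and 0.81) and 2 (0.47 and 0.55) met the bound too. Their interquartile ranges were 0.53 to 0.84 against 0.10 and 0.09 here. A mix exceeds its parts only by noise, which was not measured, so this cannot decide. Over 1.5-fold outside the range lay 15 of 10723 genes, against 427 to 1351 in the other libraries. COL2A1 (42.8, 26.6 and 11.4 CPM in replicates 1, 2 and 3) and GFAP (10.5, 5.43 and 2.54) were below and RN18S (820, 613 and 1400) above. An ordinary replicate on a shared tissue axis also stays open, since its residual spread was 0.55 of the smallest in the other groups, above the bound of 0.5. Without this library untreated against normal called 3145 genes in place of 5692, and no biological explanation was tested.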
